A study of Mus musculus with 20 samples.

How the data were processed

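The series holds RNA-seq of macrophages and monocytes sorted from MC38 tumours, grown from a mouse colon carcinoma line, in control mice and in mice given an antibody to PD-L1, the ligand of the inhibitory receptor PD-1. RNA was isolated 7 days after treatment began. The labels name 4 groups of 5 libraries, 20 in all, and give no batch. All control libraries have lower sample numbers than all treated ones. Treatment therefore cannot be told apart from an effect that follows the order of these numbers. The markers and gates of the sort are not given in the sources used here. The labels also do not say that the 5 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Replicates were numbered in the order of deposit, which only names them.

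Libraries were made from 0.1 ug of total RNA with a stranded total RNA kit, per the labels' protocols, although the molecule label names polyA RNA. Per the submitters' processing notes, reads were aligned with GSNAP to GRCm38. The aligner's version, the gene annotation, the counting tool and the strand setting are not given in the sources used here. Per the file headers, each file gives for 36528 gene models a count of uniquely aligned reads and an nRPKM value. The deposited RPKM values were checked against the counts: within a gene they are the count divided by a length and a library size factor, with factors between 0.84 and 1.24 of their mean, and they were not used for tests. The deposited counts were used unchanged. Reads from near-identical genes were dropped or split by unique alignment to an unknown degree, so members of the H2, Gbp, Tgtp, Oas, Ifit and Ly6 families are reported as uncertain, as are genes that overlap an antisense partner.

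Gene models are given by Entrez number. Symbols and coordinates were taken from the RefSeq annotation of GRCm38.p6, the build the submitters name, which matched 31049 models (85.0%) holding 97.97% of the counts. The 5479 models without a match stayed in library sizes and tests under their number.

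Depth was even, from 30191509 to 36514133 counts per library. A floor of 3 counts equals 0.099 CPM in the shallowest library, and 1 read equals 0.0331 CPM there. Such floors cover counting error only. Between replicates of one group, chi-square values per degree of freedom were far above 1, the lowest being 22.06, so the libraries of a group are not copies of one another.

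Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low genes were removed with filterByExpr, leaving 15390 genes, and libraries were scaled by TMM. A quasi-likelihood model with one mean per group was fitted to all 20 libraries, so that the groups shared one estimate of the spread. The contrasts tested were anti-PD-L1 against control in macrophages and in monocytes, the difference of those effects, and macrophages against monocytes in control and in treated tumours. A gene was called past a Benjamini-Hochberg adjusted p of 0.05. CPM values in the text are scaled by TMM library sizes and given as mean ± SD.

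Before the data were examined, 34 gene lists with at least 5 tested members were fixed, covering immune and metabolic programmes, the sorted cell types, other cell types and RNA quality. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes 0.01), adjusted over the lists within a contrast. Camera was repeated with an estimated correlation, and the self-contained test fry was run. Members past the threshold were counted over all genes tested and adjusted over the list alone. The level of a list in a library is the mean log2 CPM of its members, and groups of 5 were compared on it by two-sided exact permutation tests over 252 splits, adjusted over 20 such tests.

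The genes named in the text follow a rule fixed together with the lists. For each treatment contrast it takes up to 4 called members of each biological list with the smallest p. It adds the 6 highest and 6 lowest fold changes among called genes with a mean log2 CPM of at least 2 whose treated libraries all lie on one side of all control libraries. Gene models without an assigned name and receptor segments were left out. Genes always included were, among others, Cd274, Cxcl9, H2-Ab1, Cd40, Nos2, Arg1 and Mrc1. Some genes that meet the rule are not reported here. Between cell types in control tumours, it takes the 8 highest and 8 lowest and up to 4 members of each list for the sorted cell types. Genes named outside the rule are said to be chosen after their values were seen.

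The fits were tested on simulated counts with known changes. In the macrophage contrast 37.3%, 55.2% and 86.4% of genes changed by 1.5, 2 and 4 times were recovered, and in the monocyte contrast 34.3%, 61.2% and 86.4%, with 7 and 9 unchanged genes called among 15390. A shifted IFN-gamma list was recovered in both contrasts and 0 of the other 33 lists were called. The simulated genes were drawn independently of one another, without the correlation between genes, the pairing or the fibroblast marker RNA of the real libraries. This run therefore cannot show how often camera calls unchanged lists in the real data.

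Each result was also computed with RLE size factors, no low-count filter, a filter at a mean CPM of 1, DESeq2 1.42.0, limma-voom with quality weights, a fit of the compared groups alone, leaving out each library in turn, and a replicate block. The block treats a macrophage library and the monocyte library with the next sample number as one tumour, which the labels do not state. Deviations from the group means correlated within all 10 such pairs (r from 0.22 to 0.72). In 9 of 10 pairs the own partner gave the highest value among the monocyte libraries of the same treatment. Over 10739 genes without a clear slope on the fibroblast marker level described below, r ran from 0.08 to 0.56. On this ground the numbers were taken to pair the libraries, and blocked values are given where they change a result. The block was random in the treatment contrasts (limma duplicateCorrelation with statmod 1.5.0, estimated at 0.53) and fixed in the others. For genes in the treatment contrasts it was fitted in limma-voom instead of edgeR, so the tool changed together with the block.

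A level of fibroblast marker RNA that differed between libraries led to a pair of alternatives chosen after seeing the data. One adds the mean log2 CPM of the 19 fibroblast markers as a covariate, also in linear models of the IFN-gamma and cell cycle scores per library within each cell type. The other leaves out 6 control libraries, the 3 of each cell type with the highest level. That choice was made by a measured level and among controls alone, so it moves the control groups toward the treated ones by its construction. Recovery in the simulated macrophage contrast fell to 19.4%, 46.3% and 74.2% with the covariate and to 13.4%, 32.8% and 65.2% without the 6 libraries. In the monocyte contrast it was 19.4%, 44.8% and 81.8% with the covariate and 16.4%, 35.8% and 74.2% without them. The results were also set against 100 of the 126 splits of the 10 neighbouring pairs into groups of 5. Figures were drawn with matplotlib 3.10.9.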

Results

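RNA-seq profiles were available for macrophages and monocytes sorted from MC38 tumours, a transplantable mouse colon carcinoma model, in control mice and in mice treated with an antibody to PD-L1. Each of the 4 groups held 5 libraries taken 7 days after treatment began, with 30191509 to 36514133 counts per library. The design asks how macrophages and monocytes in the tumour changed under anti-PD-L1, whether they changed alike, and how the sorted populations differed from each other. Unless stated otherwise, fold changes are log2 values with standard errors from edgeR's quasi-likelihood fit, adjusted p-values are from Benjamini-Hochberg correction of its test over 15390 genes, and levels are CPM as mean ± SD with n = 5. Gene coordinates are those of the RefSeq annotation on GRCm38.

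In macrophages, anti-PD-L1 was followed by higher expression of PD-1 ligand, interferon-induced and antigen presentation genes. Pdcd1lg2 (Entrez 58205, chromosome 19, 29410919 to 29472927), which encodes the PD-1 ligand PD-L2, rose from 5.55 ± 3.08 to 31.8 ± 36.1 CPM (log2 fold change 2.52, SE 0.54, adjusted p = 0.036). Treated macrophage replicate 4 stood highest for Pdcd1lg2, at 6.59 log2 CPM against 3.73 to 4.16 in the other 4, and without it the log2 fold change was 1.57 and did not pass (adjusted p = 0.0794). Cd274 (Entrez 60533, chromosome 19, 29362107 to 29388095), which encodes the antibody target PD-L1, rose from 231 ± 70.6 to 434 ± 94.8 CPM (0.91, SE 0.24, adjusted p = 0.044). Pecam1 (Entrez 18613, chromosome 11, 106654213 to 106715281), an adhesion molecule of endothelium and leukocytes, rose from 58.4 ± 11 to 142 ± 27.5 CPM and had the smallest p among the named genes (1.28, SE 0.15, adjusted p = 0.00059). Of 15390 genes, 266 rose and 449 fell, a balance that turned in limma-voom, where 333 rose and 149 fell, and in 12 of 20 fits without 1 library.

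Of the 35 tested IFN-gamma response genes, 11 rose and 0 fell, and 29 rose when adjusted over the list alone. The list's median log2 fold change was 0.62 (camera adjusted p = 1.91e-16, adjusted p = 0.403 with an estimated correlation). Il18bp, the secreted inhibitor of interleukin-18, rose by 1.02 (SE 0.22), and the interferon-induced GTPase genes Gbp3, Tgtp1 and Tgtp2 by 0.53 (SE 0.12), 1.45 (SE 0.34) and 0.68 (SE 0.17). The type I interferon list had a median of 0.36 with 2 of 30 members higher, Zbp1 and Ifi44, and 11 adjusted over the list alone (camera adjusted p = 3.4e-09, adjusted p = 0.403 with an estimated correlation). With the neighbouring libraries as a block, fry gave an adjusted p of 0.00748 for the IFN-gamma list and 0.0534 for the type I list, and Zbp1 and Ifi44 did not pass (blocked adjusted p = 0.058 and 0.078). Cxcl9, a chemokine that attracts T cells, was at 1180 ± 356 CPM in controls and 1680 ± 210 after treatment (0.52, SE 0.23, adjusted p = 0.18) and did not pass the test. The mean level of the IFN-gamma list was 6.18 ± 0.32 in control and 6.86 ± 0.29 log2 CPM in treated macrophages (n = 5 each, exact permutation p = 0.0159, adjusted p = 0.0454).

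Antigen presentation lists moved the same way. Of 20 MHC class I presentation genes, 4 rose (13 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 1.56e-10, adjusted p = 0.403 with an estimated correlation). These were H2-T23 (0.75, SE 0.15), H2-K1 (0.44, SE 0.11), H2-D1 (0.44, SE 0.12) and Tapbpl (0.59, SE 0.14), genes of class I molecules and of their peptide loading. Of 11 MHC class II genes, H2-DMa, which loads peptide on class II, rose by 0.51 (SE 0.14; blocked adjusted p = 0.053), and 5 rose adjusted over the list alone. The class II median was 0.53 (camera adjusted p = 2.26e-05, adjusted p = 0.403 with an estimated correlation). H2-Ab1, a class II chain, was higher in all 5 treated than in all 5 control libraries, 8280 ± 1040 against 5130 ± 1490 CPM, with an adjusted p of 0.091 (0.69, SE 0.25). Counts of H2, Gbp and Tgtp genes are uncertain because reads shared with close relatives were not kept by unique alignment.

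Of 23 inflammatory activation genes, Ccl5, Il27, Ebi3 and Tlr4 rose, a T cell chemokine, a pair of cytokine subunits and the receptor for endotoxin. Their log2 fold changes were 1.20 (SE 0.29), 0.75 (SE 0.19), 0.45 (SE 0.09) and 0.34 (SE 0.09), and 9 members rose and 2 fell adjusted over the list alone. With the replicate block Il27 and Tlr4 did not pass (adjusted p = 0.055 and 0.072). The list's median was 0.34 and its mean 0.10 (camera adjusted p = 0.000449, adjusted p = 0.403 with an estimated correlation, blocked fry adjusted p = 0.079). Of 26 alternative activation genes, 3 rose, also adjusted over the list alone. They were Pdcd1lg2, the interleukin-4 receptor gene Il4ra (0.57, SE 0.12) and the transglutaminase gene Tgm2 (0.83, SE 0.22). That list's median was 0.34 (camera adjusted p = 0.00204, adjusted p = 0.403 with an estimated correlation, blocked fry adjusted p = 0.079), and without macrophage control replicate 2 it was 0.35 and no longer passed (adjusted p = 0.0957). Nos2, the inducible nitric oxide synthase, was at 88.0 ± 28.7 and 183 ± 53.6 CPM (1.06, SE 0.35, adjusted p = 0.071), and the arginase gene Arg1 at 401 ± 105 and 748 ± 464 CPM (0.90, SE 0.38, adjusted p = 0.15). Cd40 (0.65, SE 0.19, adjusted p = 0.055) and the mannose receptor gene Mrc1 (-0.14, SE 0.30, adjusted p = 0.82) did not pass either. In the checkpoint and costimulation list, Vsir (0.53, SE 0.11), Cd274 and Pdcd1lg2 rose out of 22 genes, and 5 adjusted over the list alone. Its median was 0.20 (camera adjusted p = 0.000449, adjusted p = 0.403 with an estimated correlation, blocked fry adjusted p = 0.0513), and 0.06 with the fibroblast marker level as a covariate, which ended the call (camera adjusted p = 0.325).

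Large separated rises beside Pdcd1lg2 and Pecam1 were in Ly6i (1.91, SE 0.44), the formyl peptide receptor gene Fpr1 (1.46, SE 0.32) and Tarm1 (1.35, SE 0.30), and of these Ly6i and Tarm1 did not pass with the replicate block (adjusted p = 0.063 and 0.094). Treated macrophage replicate 4 stood highest for Ly6i, at 6 log2 CPM against 3.6 to 4.25 in the other treated macrophage libraries. The same library stood highest for Tarm1, at 4.81 against 3.13 to 3.56. Mmp13, a collagenase, rose from 74.5 ± 12.5 to 163 ± 22.3 CPM (1.13, SE 0.19, adjusted p = 0.018). The largest separated falls were in Angptl2, a secreted angiopoietin-like protein, which fell by 1.48 (SE 0.31), in Ackr3, an atypical chemokine receptor, which fell by 1.40 (SE 0.31), and in Adgrl2, Ddah2, Mfge8 and Asap2, at -1.38, -1.34, -1.28 and -1.16 (blocked adjusted p = 0.059 for Asap2). Fibroblast marker RNA moved with the genes that fell. Of 19 fibroblast markers, 9 fell and 16 fell adjusted over the list alone, with a median of -2.71 (camera adjusted p = 7.32e-09, adjusted p = 0.403 with an estimated correlation). The collagen gene Col3a1, chosen like S100a9 below after its values were seen, was at 538.5 CPM in control and 59.4 in treated macrophages, and Sparc, a matrix protein gene, at 115 ± 88.7 and 17.6 ± 14. The mean level of the list was 2.98 ± 1.53 log2 CPM in control and 0.91 ± 0.76 in treated macrophages (n = 5 each, exact permutation p = 0.0317, adjusted p = 0.0704). Within the groups, 434 of the 449 genes that fell (96.7%) had a positive slope on that level, 343 of them past its test, against a positive slope in 48.5% of all genes tested. Matrix and angiogenesis genes divided, with Mmp9 (-3.00, SE 0.77), Vegfc (-2.48, SE 0.64) and Sparc (-2.71, SE 0.73) among 4 of 25 that fell and Mmp13 the 1 that rose (5 and 2 adjusted over the list alone). With the replicate block Mmp9, Vegfc and Sparc did not pass (adjusted p = 0.18, 0.13 and 0.080). The list's median was 0.05 and its mean -0.45 (camera adjusted p = 0.866).

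With the fibroblast marker level as a covariate, an alternative chosen after seeing the data, 2 genes passed in macrophages, Pecam1 (1.30) and Cd109 (-2.12), the latter named after its values were seen. Without the 6 control libraries highest in fibroblast markers, 64 genes rose and 6 fell. The median of the 449 lower genes went from -2.48 to -0.41 with the covariate, and that of the 266 higher genes from 0.57 to 0.42. All 266 higher genes and 92.2% of the 449 lower genes kept their side. Both sets were chosen in these same libraries, so a kept side is not separate support. The IFN-gamma list kept a median of 0.53 with the covariate and 0.67 without the 6 libraries. Fry without a block ended 14 list calls in macrophages, with a lowest adjusted p of 0.0214 over the 34 lists. The covariate ended 9 list calls in macrophages, those of NF-kB targets (camera adjusted p = 0.898), chemokines (0.0647), checkpoint genes, cell cycle, lysosome (0.287), macrophage markers (0.812), fibroblast markers (0.898), ribosomal proteins (0.213) and histones (0.354). For the fibroblast markers this follows by construction, since the covariate is their own mean level. With the neighbouring libraries as a replicate block in limma-voom, 195 genes rose and 48 fell, and DESeq2 called 1834. The count moved by over 1.5 times on leaving out any of 15 libraries. It fell to 14 without treated macrophage replicate 4 or control macrophage replicate 5, 19 without control macrophage replicate 1, 35 without treated macrophage replicate 1, 77 without control monocyte replicate 1, 124 without treated macrophage replicate 3 and 217 without treated macrophage replicate 5. It was 350 without control macrophage replicate 3, 382 without control monocyte replicate 2 and 411 without treated monocyte replicate 4. It increased to 1081 without control monocyte replicate 4, 1212 without treated monocyte replicate 3, 1415 without control macrophage replicate 2, 1747 without control monocyte replicate 5 and 1928 without control macrophage replicate 4. Of the 45 named genes past the test in macrophages, Mmp13 and Pecam1 passed in every fit that left out 1 library.

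**Figure D1:**
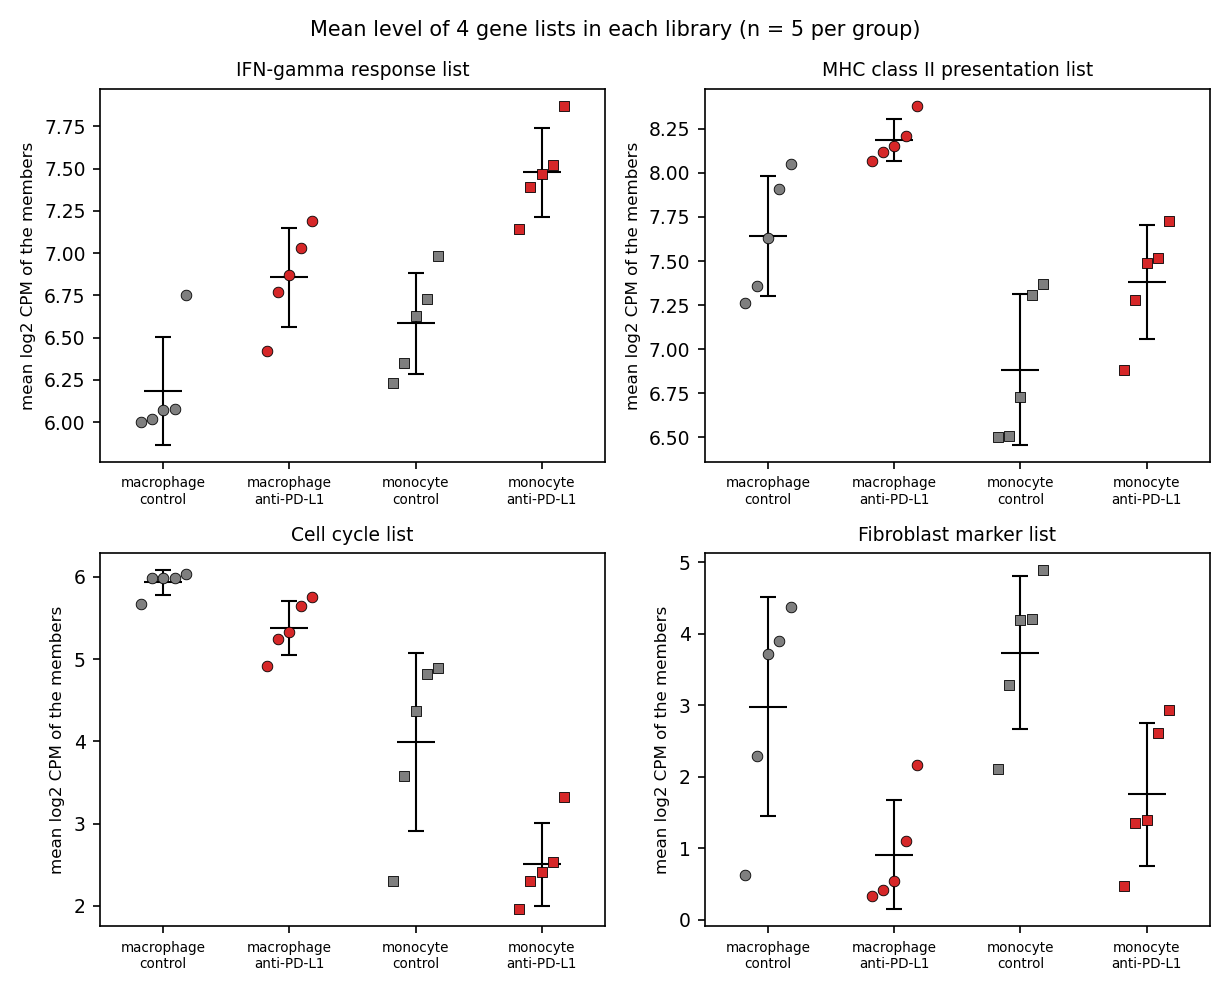
Mean log2 CPM of the members of 4 gene lists in each library, with circles for macrophages, squares for monocytes, grey for control, red for anti-PD-L1, and bars for the mean and SD of 5 libraries. The IFN-gamma response list is at 6.18 in control and 6.86 in treated macrophages and at 6.58 and 7.48 in monocytes, while the fibroblast marker list is at 2.98 and 0.91 and at 3.74 and 1.75.

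In monocytes, interferon-induced, antigen presentation and inflammatory genes rose after anti-PD-L1 and cell cycle genes fell. Of 35 IFN-gamma response genes, 29 rose and 0 fell (30 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 1.23e-15, adjusted p = 0.425 with an estimated correlation). Cd274 rose from 322 ± 82.1 to 822 ± 312 CPM (1.35, SE 0.24, adjusted p = 0.0034) and Cxcl9 from 582 ± 187 to 1080 ± 260 (0.89, SE 0.23, adjusted p = 0.012). Of 38 cell cycle genes, 34 fell (37 adjusted over the list alone), with a median of -1.69 (camera adjusted p = 1.5e-15, adjusted p = 0.425 with an estimated correlation). Of 15390 genes, 1526 rose and 2374 fell.

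Among the interferon-induced genes of monocytes, the GTPase genes Tgtp2, Gbp6 and Irgm1 rose by 1.05 (SE 0.17), 1.16 (SE 0.19) and 0.94 (SE 0.16), and Il18bp by 1.30 (SE 0.22). Of 30 type I interferon genes, 23 rose (28 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 1.21e-12, adjusted p = 0.425 with an estimated correlation). They included Ifi44 (1.16, SE 0.19), the transcription factor gene Irf7 (0.93, SE 0.19) and the oligoadenylate synthetase family genes Oasl2 (0.83) and Oas1g (0.81). Of 20 MHC class I genes, 18 rose and all 20 rose adjusted over the list alone, with a median of 0.52 (camera adjusted p = 5.42e-11, adjusted p = 0.425 with an estimated correlation). Examples were H2-M3 (0.51), H2-K1 (0.56), H2-Q4 (0.52) and H2-T23 (0.72). Of 11 MHC class II genes, 3 rose and 5 rose adjusted over the list alone. These 3 were H2-DMa (0.48), the invariant chain gene Cd74 (0.67) and Ciita (0.87), the regulator of class II transcription. The class II median was 0.48 (camera adjusted p = 0.00425, adjusted p = 0.554 with an estimated correlation), and H2-Ab1 was at 2360 ± 877 and 3680 ± 957 CPM (0.64, SE 0.25, adjusted p = 0.062, with the replicate block 0.034). The mean level of the IFN-gamma list was 6.58 ± 0.30 in control and 7.48 ± 0.26 log2 CPM in treated monocytes (n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0397).

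Of 23 inflammatory activation genes, 11 rose in monocytes, and 15 rose and 1 fell adjusted over the list alone, with a median of 0.60 (camera adjusted p = 1.66e-06, adjusted p = 0.425 with an estimated correlation). Nos2 rose from 189 ± 74.8 to 609 ± 336 CPM (1.69, SE 0.35, adjusted p = 0.0051), Slamf7 by 1.34 (SE 0.24), Ebi3 by 0.63 and Tlr4 by 0.60. Of 21 NF-kB target genes, 5 rose (10 adjusted over the list alone), among them Tnfaip2 (1.07), Sod2 (0.64), Tnfaip3 (0.55) and Birc3 (0.43), with a median of 0.41 (camera adjusted p = 7.57e-06, adjusted p = 0.425 with an estimated correlation). Without the 6 control libraries highest in fibroblast markers, Tnfaip2, Sod2, Tnfaip3 and Birc3 were at 0.89, 0.28, 0.31 and 0.14 and did not pass. Of 23 chemokine genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with Cxcl11 at 1.12, Cxcl16 at 0.61 and Cxcl2 at 0.70, but the list did not pass (median 0.18, camera adjusted p = 0.0842). Of 22 checkpoint and costimulation genes, 6 rose (9 adjusted over the list alone), including Cd86 (0.60), Cd40 (0.78, adjusted p = 0.0095) and Siglec1 (0.64), with a median of 0.38 (camera adjusted p = 7.82e-05, adjusted p = 0.425 with an estimated correlation). Without the 6 control libraries, Cd86, Cd40, Siglec1 and Cd274 were at 0.32, 0.38, 0.52 and 1.23 and did not pass. Of 26 alternative activation genes, 4 rose (2 adjusted over the list alone), namely the interleukin-1 antagonist gene Il1rn (1.08), Il4ra (0.46), Pdcd1lg2 (1.55) and the lectin gene Clec7a (0.44), of which Pdcd1lg2 and Clec7a did not pass with the replicate block (adjusted p = 0.061 each), while the list did not pass (median 0.06, camera adjusted p = 0.118). Arg1 was at 877 ± 246 and 1530 ± 815 CPM (0.80, SE 0.38, adjusted p = 0.12) and Mrc1 at 21.3 ± 9.09 and 18.9 ± 6.88 CPM (-0.17, SE 0.31, adjusted p = 0.71).

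The cell cycle genes with the smallest p in monocytes were Hmmr (-2.97, SE 0.54), the cyclin genes Ccnb2 (-1.67, SE 0.31) and Ccna2 (-1.73, SE 0.33), and the mitotic kinase gene Plk1 (-2.14, SE 0.41), of which Hmmr did not pass with the replicate block (adjusted p = 0.065). The mean level of the list was 3.99 ± 1.08 in control and 2.50 ± 0.51 log2 CPM in treated monocytes (n = 5 each, exact permutation p = 0.0397, adjusted p = 0.0794). Fibroblast marker RNA moved with this list. The cell cycle median was -1.22 with the fibroblast marker level as a covariate, with 1 slope for both cell types. It was -0.47 without the 6 control libraries highest in that level. Of 19 fibroblast markers, 11 fell (12 adjusted over the list alone), with a median of -2.08 (camera adjusted p = 3.05e-05, adjusted p = 0.554 with an estimated correlation). Col3a1 was at 882.6 CPM in control and 117 in treated monocytes. The mean level of the fibroblast list was 3.74 ± 1.07 and 1.75 ± 1.01 log2 CPM (n = 5 each, exact permutation p = 0.0317, adjusted p = 0.0704). Within the groups, 2282 of the 2374 genes that fell (96.1%) had a positive slope on that level, 1153 of them past its test.

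The largest separated rises in monocytes were in Slc4a11 (1.90, SE 0.34), Nos2, Tgtp1 (1.69, SE 0.34), Clic5 (1.60, SE 0.37), Serpina3f (1.59, SE 0.23) and the leukotriene receptor gene Cysltr2 (1.59, SE 0.25). The largest separated falls were in the endopeptidase gene Mme (-3.43, SE 0.93), Angptl2 (-2.25, SE 0.32), the complement protease gene Masp1 (-2.07, SE 0.37), Igfbp6 (-1.99, SE 0.53), Lix1l (-1.65, SE 0.26) and Fam135a (-1.60, SE 0.30). Mmp13 rose from 17.0 ± 2.43 to 41.7 ± 16.9 CPM (1.29, SE 0.19). The protease inhibitor gene Timp2 (-1.84, SE 0.36), the gelatinase gene Mmp2 (-2.44, SE 0.51) and Sparc (-2.64, SE 0.73) were the 3 of 25 matrix and angiogenesis genes that fell, and 4 rose, with the same counts adjusted over the list alone (median 0.08, mean -0.24, camera adjusted p = 0.73).

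With the fibroblast marker level as a covariate, 8 genes rose and 3 fell in monocytes. Among them were Ifi44 (1.32), Angptl2 (-1.59) and, named after their values were seen, H2-Q7 (1.08), Pecam1 (1.14), Prune2 (-1.41) and the sterol synthesis gene Hsd17b7 (-1.07). Without the 6 control libraries, 67 rose and 16 fell. The median of the 1526 higher genes was 0.45 in all libraries, 0.32 with the covariate and 0.26 without the 6 libraries. All 1526 kept their side in both, as did 96.5% and 96.8% of the lower genes measured. Both sets were chosen in these same libraries, so a kept side is not separate support. The covariate ended the monocyte list calls of lipid handling (camera adjusted p = 0.0993) and, by construction, of fibroblast markers (0.876). Leaving out the 6 control libraries ended 6 list calls in monocytes. Fry without a block ended 5 list calls in monocytes, with a lowest adjusted p of 0.000761 over the 34 lists. The count of 3900 genes was 2019 when the monocyte groups were fitted alone. It was 1883 without control monocyte replicate 3, 2211 without control monocyte replicate 4, 2451 without treated monocyte replicate 2, 2562 without treated monocyte replicate 1 and 2594 without treated monocyte replicate 4.

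**Figure D2:**
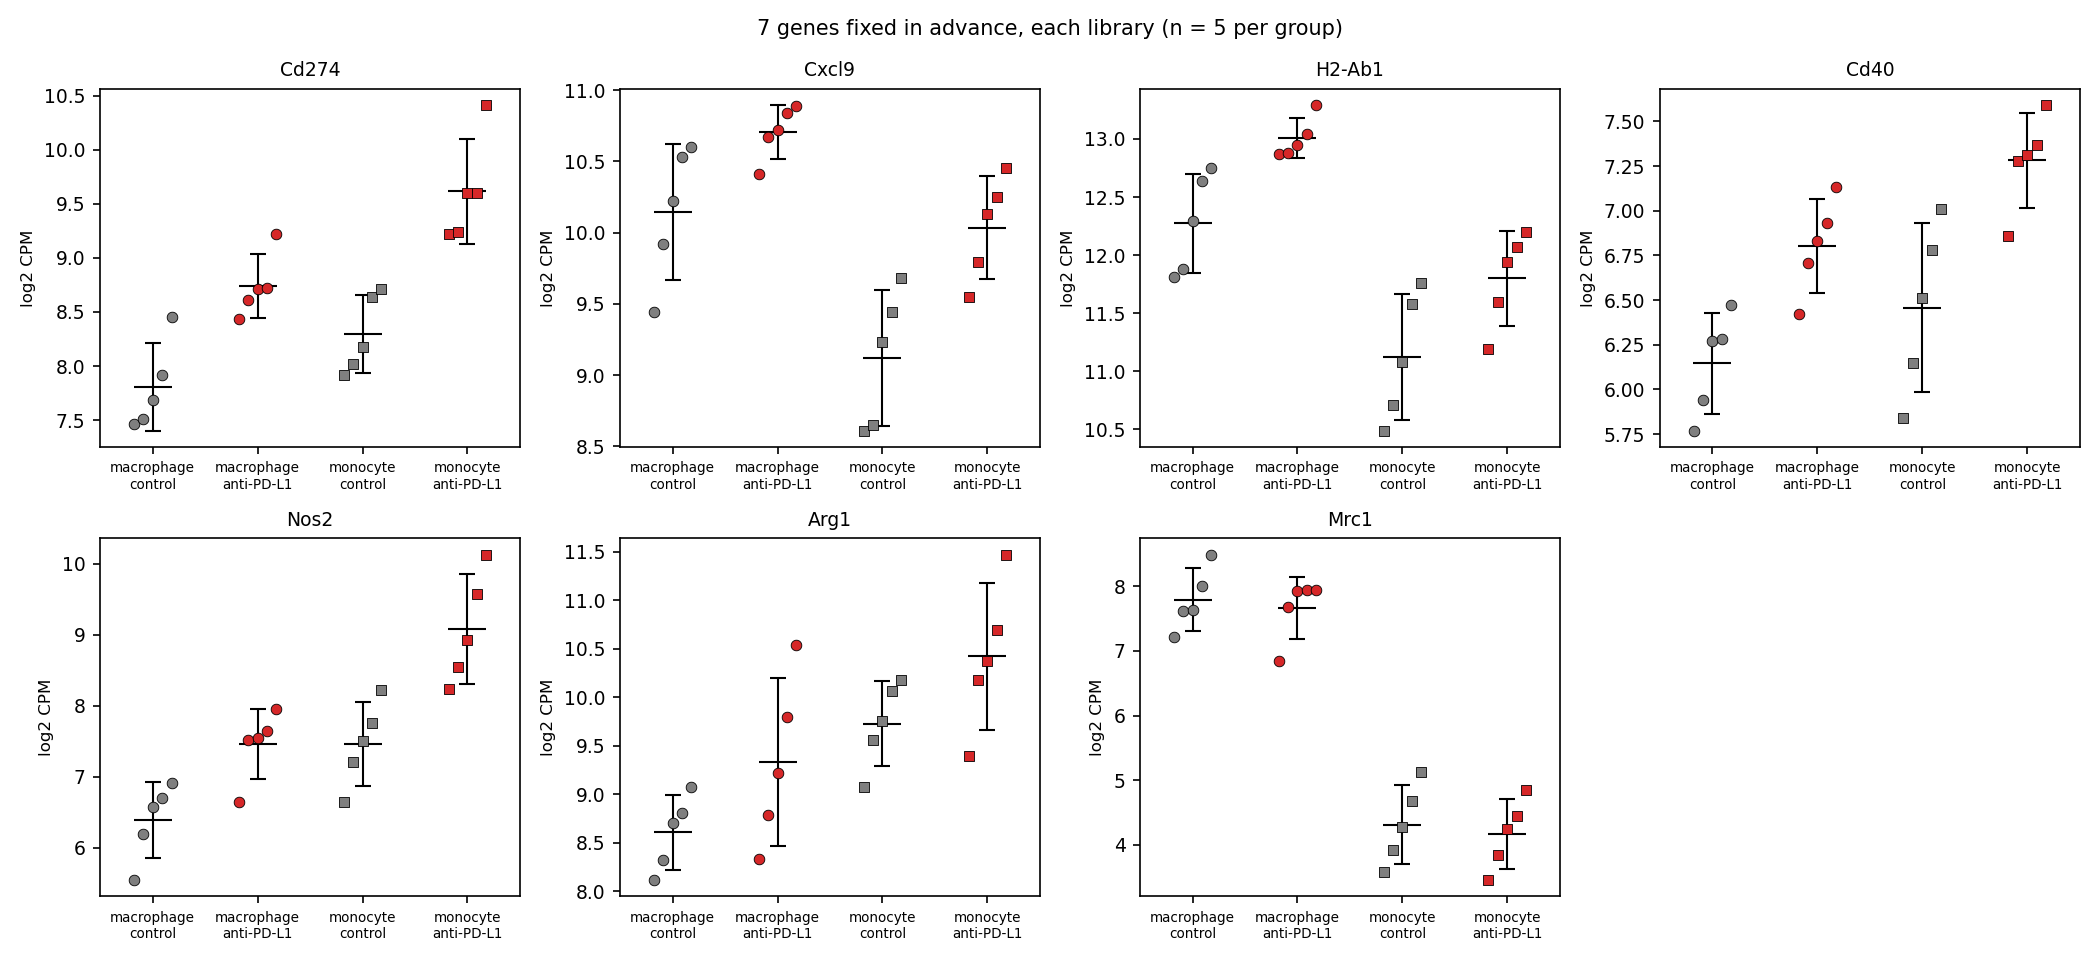
Log2 CPM of 7 genes named before the data were examined, in each library, with circles for macrophages, squares for monocytes, grey for control, red for anti-PD-L1, and bars for the mean and SD of 5 libraries. Cd274 passed the test in both cell types, Cxcl9, Cd40 and Nos2 passed in monocytes, and H2-Ab1, Arg1 and Mrc1 passed in neither.

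Genes called in macrophages were mostly called in monocytes too. Of the 266 genes that rose in macrophages, 207 also rose in monocytes, and of the 449 that fell, 353 also fell. No gene was called in opposite directions. Interferon-induced genes in both sets included Cd274, Il18bp, Tgtp1 and Ifi44. Across 15390 genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.821 and Spearman rho = 0.709, with the same sign in 77.6%. The contrasts share no library, but neighbouring libraries correlate, and with the treatment labels moved over the neighbouring pairs the median correlation was 0.55. The correlation was 0.354 with the fibroblast marker level as a covariate and 0.418 without the 6 control libraries.

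A direct test of whether macrophages and monocytes responded differently called 0 genes in edgeR. At an unadjusted p under 0.05 there were 980 genes, where 770 are expected by chance. With the neighbouring libraries as a replicate block, 3 genes passed: the interferon-induced GTPase gene Iigp1, higher by less in macrophages (0.55 against 1.32 in monocytes, difference -0.79, adjusted p = 0.00924), Samsn1 (difference -0.60, adjusted p = 0.0456) and the chondroitin polymerising factor gene Chpf (difference 2.24, adjusted p = 0.0456). DESeq2 called 5 genes, Masp1, Sorbs3, Prune2, Rgl3 and R74862, all with a positive difference. Apart from Masp1, these genes were named after their values were seen. Without control monocyte replicate 5 the count was 89, all with a positive difference, and without control macrophage replicate 4 it was 1, Prune2.

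As groups, cell cycle genes fell by less in macrophages than in monocytes, with a median difference of 1.12 over 38 genes (camera adjusted p = 6.73e-14), and in macrophages 0 of 38 passed (median -0.55, camera adjusted p = 3.49e-05, adjusted p = 0.667 with an estimated correlation, blocked fry adjusted p = 0.411). The mean level of the cell cycle list in macrophages was 5.93 ± 0.15 in control and 5.38 ± 0.34 log2 CPM after treatment (n = 5 each, exact permutation p = 0.0159, adjusted p = 0.0454), and with the fibroblast marker level as a covariate the median was -0.15 and its call ended (camera adjusted p = 0.8). That covariate has 1 slope for both cell types. In the macrophage groups alone the slope was -0.04 (SE 0.08), and the treated minus control difference of the score stayed at -0.63 (SE 0.24). The rise in macrophages was smaller for the IFN-gamma list (difference -0.24, adjusted p = 0.00227), type I interferon (-0.28, adjusted p = 0.00014), MHC class I (-0.12, adjusted p = 0.0132), inflammatory activation (-0.26, adjusted p = 0.00167) and NF-kB targets (-0.20, adjusted p = 0.000421), all by camera. The immediate-early list had a difference of -0.21 (adjusted p = 0.00167). Each of these 7 lists had an adjusted p of 0.922 with an estimated correlation, and 0 of their members passed over all genes in edgeR. Fry without a block ended all 7 calls, with a lowest adjusted p of 0.914 over the 34 lists. With the neighbouring pair as a fixed block, camera at the preset correlation gave adjusted p = 5.06e-06 for IFN-gamma, 1.3e-06 for type I interferon, 0.00195 for class I, 0.000372 for inflammatory activation, 2.37e-05 for NF-kB targets, 2.13e-08 for cell cycle and 0.00025 for immediate-early genes. With the fibroblast marker level as a covariate, the cell cycle difference was 1.07 (adjusted p = 1.15e-13) and the IFN-gamma difference -0.23 (adjusted p = 0.00253), and without the 6 control libraries they were -0.08 and 0.03. The 1.07 rests on the slope shared by the cell types. In the monocyte groups alone the slope was 0.66 (SE 0.18), and the treated minus control difference of the cell cycle score was -0.17 (SE 0.48). Of fits without 1 library, those without control macrophage replicate 3, treated monocyte replicate 2 or treated macrophage replicate 5 ended the IFN-gamma call, with differences of -0.06, -0.12 and -0.08. The fit without control monocyte replicate 4 ended the NF-kB call (-0.02) and the immediate-early call (-0.07), the latter also ended without control macrophage replicate 3 (-0.09). The class I call ended in 8 of 20 such fits.

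**Figure D3:**
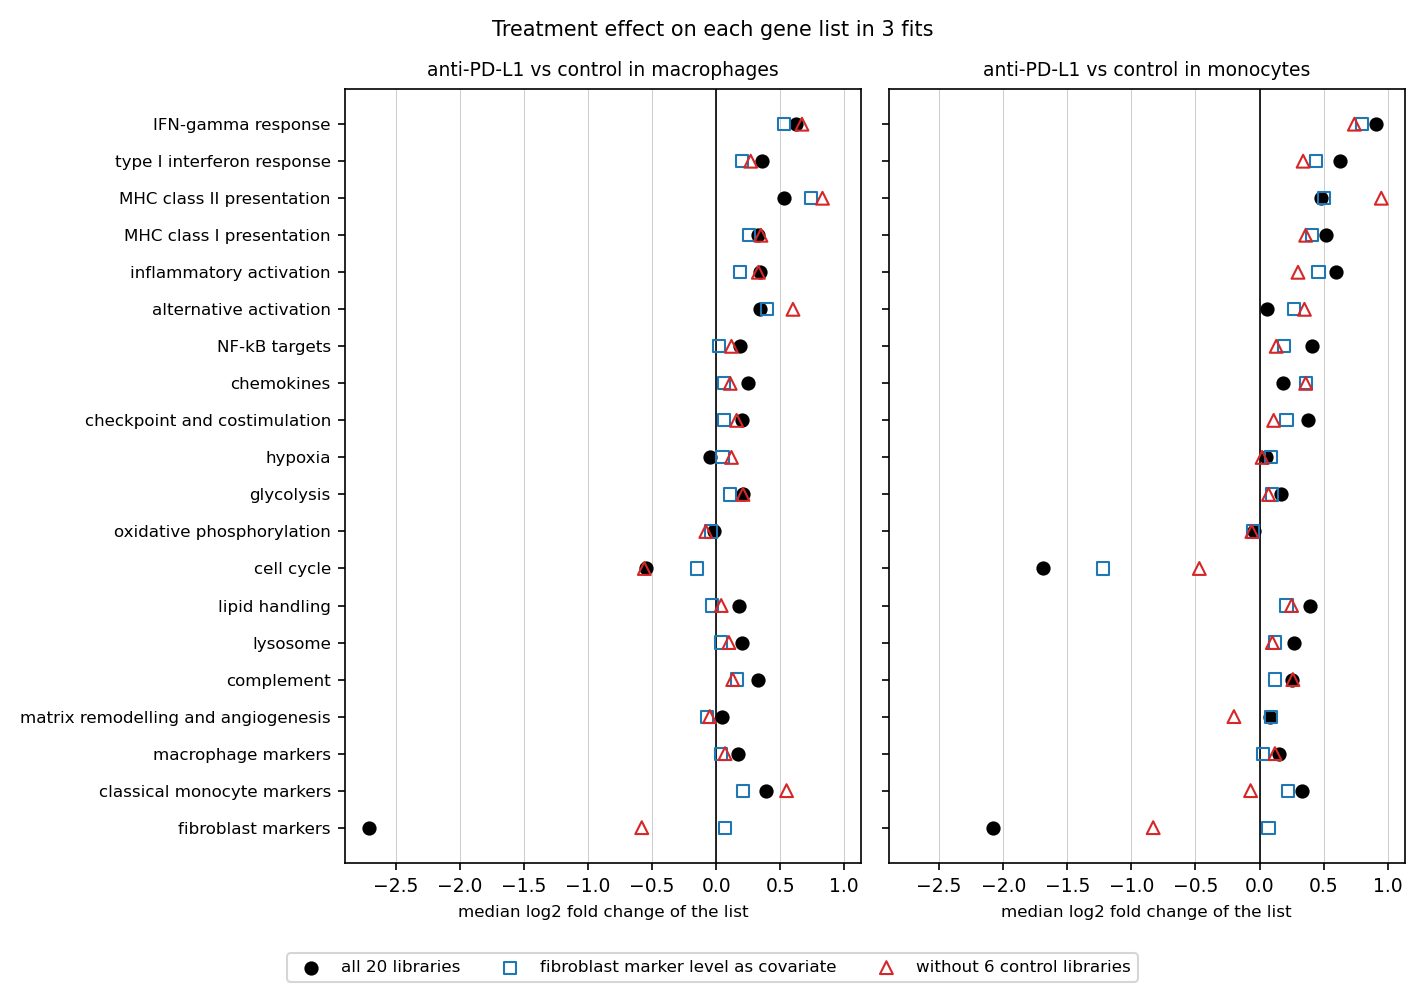
Median log2 fold change after anti-PD-L1 of 20 gene lists in macrophages and monocytes, in the fit of all 20 libraries (black), with the fibroblast marker level as a covariate (blue squares) and without 6 control libraries (red triangles). The IFN-gamma medians lie at 0.62, 0.53 and 0.67 in macrophages and at 0.91, 0.80 and 0.74 in monocytes. The fibroblast markers move from -2.71 to 0.07 with the covariate in macrophages, which follows by construction, since the covariate is their own mean level.

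Macrophages and monocytes from control tumours differed in 6784 genes, 3700 higher in macrophages and 3084 lower. The complement C1q genes, typical of tissue macrophages, were higher in macrophages, with C1qa at 4000 ± 708 against 554 ± 166 CPM in monocytes (2.85, SE 0.18, adjusted p = 7.5e-10), C1qb at 2.39 (SE 0.18) and C1qc at 2.79 (SE 0.17). Of 25 macrophage markers, 18 were higher and 0 lower (18 and 1 adjusted over the list alone), with a median of 1.48 (camera adjusted p = 3.54e-09, adjusted p = 0.0949 with an estimated correlation). Of 20 classical monocyte markers, 19 were lower in macrophages, also adjusted over the list alone, with a median of -2.98 (camera adjusted p = 1.25e-17, adjusted p = 0.0465 with an estimated correlation). Haptoglobin (Hp) differed by -7.54 (SE 0.41), the chitinase-like gene Chil3 by -7.92 (SE 0.61), Ly6c2 by -7.39 (SE 0.45), Plac8 by -6.57 (SE 0.48) and Gsr by -3.10 (SE 0.18). Of 13 nonclassical monocyte markers, 6 were lower and 4 higher, also adjusted over the list alone, with Adgre4 at -6.54 (SE 0.40), Ace at -7.01 (SE 0.45) and Nr4a1 at -2.05 (SE 0.21), and the list did not pass (median -0.41, camera adjusted p = 0.117). Cd177 and Ly6a2 were near the floor in macrophages and are given without a fold.

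Neutrophil markers were lower in macrophages as well, 14 of 15, also adjusted over the list alone, with a median of -5.52 (camera adjusted p = 1.47e-11, adjusted p = 0.0465 with an estimated correlation), and 3 of the 15 stand in another list. S100a9, a calcium-binding protein gene of neutrophils and monocytes, was at 0.237 CPM in control macrophages and 75.0 in control monocytes. The largest differences toward macrophages were in the adhesion gene Cadm1 (174 ± 38 against 4.98 ± 2.52 CPM, 5.12, SE 0.32), Asb2 (4.77), the collagen gene Col14a1 (4.71), Fcrls (4.31), Scamp5 (4.10), Rapgef5 (3.96), Klra17 (3.93) and Gas6 (3.90), a ligand of receptors for dying cells. Further genes toward monocytes were Arhgef37 (-6.79), Slpi (-6.54) and Pglyrp1 (-5.11). All 38 cell cycle genes were higher in macrophages adjusted over the list alone, 36 over all genes, with a median of 1.71 (camera adjusted p = 1.81e-12, adjusted p = 0.48 with an estimated correlation). NF-kB targets were lower in macrophages, 20 of 21 on both counts, with a median of -0.91 (camera adjusted p = 4.22e-09, adjusted p = 0.399 with an estimated correlation), as were type I interferon genes, 23 of 30 (25 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 1.35e-05, adjusted p = 0.555 with an estimated correlation). Fibroblast markers did not differ past the test, which ignores the pairing, with 0 of 19 called and a median of -0.51 (camera adjusted p = 0.155). Their mean level was higher in the monocyte library of every neighbouring control pair. It was 3.29 against 2.29, 2.11 against 0.62, 4.19 against 3.9, 4.89 against 4.37 and 4.21 against 3.72 log2 CPM. Equal levels in the sorted populations are therefore not shown.

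In treated tumours, macrophages and monocytes differed in 8294 genes, 4335 higher in macrophages and 3959 lower. All 38 cell cycle genes were higher in macrophages, with a median of 2.84 (camera adjusted p = 2.81e-15, adjusted p = 0.55 with an estimated correlation). All 20 classical monocyte markers were lower, with a median of -3.58 (camera adjusted p = 6.02e-15, adjusted p = 0.0903 with an estimated correlation). Macrophage markers were higher in 18 of 25 and lower in 2 (3 adjusted over the list alone), with a median of 1.71 (camera adjusted p = 7.1e-07, adjusted p = 0.253 with an estimated correlation). The proliferation gene Mki67 was at 173.8 CPM in treated macrophages and 15.45 in treated monocytes, against 248.2 and 39.45 in controls, a gene named after its values were seen. IFN-gamma response genes were lower in treated macrophages in 25 of 35 and higher in 2 (27 and 3 adjusted over the list alone), with a median of -0.83 (camera adjusted p = 0.000223, adjusted p = 0.595 with an estimated correlation). MHC class II genes were higher in 7 of 11, also adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.0192, adjusted p = 0.595 with an estimated correlation).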

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

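The tests in this part were written down after the results they concern had been seen, including the criterion for the regroupings of the libraries. The test of macrophage RNA in the control monocyte libraries is the exception, since its prediction was written before its result.

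The genes that fell after anti-PD-L1 moved with fibroblast marker RNA. Of them, 96.7% in macrophages and 96.1% in monocytes had a positive slope on the fibroblast marker level within the groups, and the level as a covariate took 83.5% and 68.2% off their median log2 fold change. RNA of other cells carried over in the libraries could therefore account for most of this fall. Of the 19 fibroblast markers, 2 stand in another list, and 12 and 16 had a mean of at least 1 CPM in treated macrophages and monocytes. Fewer or less active fibroblasts in treated tumours is a hypothesis that was not tested, and the sort gate is not given.

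For the rise of IFN-gamma response genes, less dilution by carried-over RNA was tested against the macrophage markers and at an equal fibroblast marker level. The IFN-gamma list rose by 0.90 more than those markers in monocytes (SE 0.23, n = 5 per group, exact permutation p = 0.00794) and by 0.60 more in macrophages (SE 0.28, exact permutation p = 0.0952). In monocytes the macrophage markers, at 7.08 and 7.07 log2 CPM, are not those of the sorted cells and may not track dilution of monocyte RNA. The classical and nonclassical monocyte marker scores went from 8.09 to 8.31 and from 5.73 to 6.13 in monocytes. With the fibroblast marker level as a covariate the IFN-gamma score still rose by 0.62 in monocytes (SE 0.24) and 0.81 in macrophages (SE 0.28). Each rise was more than 2 SE. In monocytes the slope on the level was -0.14, and dilution that follows this level is excluded there as the whole cause. In macrophages the slope was 0.07, opposite in sign to dilution, so the covariate took nothing off the rise. Since the marker comparison did not pass in macrophages, dilution stays open there. RNA of T cells could not be excluded by this test, with differences from the T cell markers of 0.78 in monocytes (SE 0.46, exact permutation p = 0.135) and 0.74 in macrophages (SE 0.60, exact permutation p = 0.254), nor could RNA of cytotoxic or NK cells, with 0.24 in monocytes (SE 0.47, exact permutation p = 0.627) and 0.34 in macrophages (SE 0.58, exact permutation p = 0.563). The T cell marker score itself showed no rise past its test. It was 0.27 ± 0.51 in control and 0.21 ± 0.93 log2 CPM in treated macrophages (exact permutation p = 0.929). In monocytes it was 0.42 ± 0.39 and 0.54 ± 0.66 (exact permutation p = 0.778). A response of the sorted cells to interferon under treatment is a hypothesis that stays open as untested.

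For the fall of cell cycle genes in monocytes, macrophage RNA in the control monocyte libraries was tested first. The cell cycle genes would need 23.6 percentage points more macrophage RNA than the macrophage markers gave (SE 7.9, larger in 5 of 5 libraries), which excludes it as the whole cause. In control monocyte replicate 5 the shares were -1.7% and -2.5%, so that library had no excess to account for. Its cell cycle score of 2.3 log2 CPM lay within the treated range of 1.96 to 3.32. RNA of the cells that bear the fibroblast markers could account for the fall, since the cell cycle score rose by 0.66 per unit of the fibroblast marker level within the monocyte groups (SE 0.18), where the difference of the group means needs 0.75. With 1 slope for both cell types the monocyte median stayed at -1.22 (camera adjusted p = 5.17e-14). For the score that shared slope was 0.26 (SE 0.13), drawn down by macrophages, where it was -0.04 (SE 0.08). The -1.22 therefore cannot decide against this explanation. Within the monocyte groups the level left a difference of -0.17 (SE 0.48), so the explanation stays open. Less division of the monocytes under treatment is a hypothesis that was not tested.

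Treatment labels were moved over the 10 neighbouring pairs of libraries in 100 splits, the real one included. As many genes as the real 715 in macrophages and 3900 in monocytes came from 2 and 2 splits, which excludes a random grouping by this criterion, with the highest other counts at 1138 and 4124. The real split puts the 3 pairs high in fibroblast markers on one side, and so do the other splits with as many genes and each of the 5 monocyte splits with the most genes, so these counts do not separate treatment from that level. Another macrophage split with these 3 pairs on one side called 1 gene at a level difference of 1.64, and the monocyte counts did not rank with it, 3686 at 2.43 and 4124 at 2.15. By the same criterion, with no correction for the number of quantities tested, a random grouping is excluded for the IFN-gamma medians of 0.62 in macrophages (2 splits, highest other 0.73) and 0.91 in monocytes (1 split, highest other 0.80). The same holds for the cell cycle median in monocytes, 1.69 in size (3 splits, highest other 1.97), and for the correlation of the treatment effects, 0.82 (3 splits, highest other 0.83, median other 0.55). These splits do not separate treatment from the fibroblast marker level for these values either, and the correlation was 0.354 with that level as a covariate. Among lists called by camera, chance cannot be excluded for the macrophage medians of type I interferon (8 splits), alternative activation (25), chemokines (8), checkpoint (6), glycolysis (11), macrophage markers (16), fibroblast markers (6), ribosomal proteins (31) and histones (9). Nor can it for the monocyte medians of MHC class II (9 splits), complement (20), cytotoxic and NK markers (11), immediate-early genes (10) and ribosomal proteins (18). The 0 interaction genes cannot be tested in this way, since all 100 splits give as many by construction (highest other 159). Chance cannot be excluded for the number of gene lists called in macrophages, 17 (17 splits, highest other 24, median other 12), in monocytes, 17 (16 splits, highest other 21, median other 13), and in the interaction, 7 (42 splits, highest other 19, median other 6). Camera at the preset correlation thus calls many lists under moved labels. For cell type labels moved within a treatment, chance can be excluded for the 6784 genes in control tumours (1 split, highest other 4462) and the 8294 in treated tumours (1 split, highest other 1). Among splits that part all 5 neighbouring pairs as the real one does, the highest other counts were 843 in 13 splits and 0 in 14, so the 4462 came from a split that keeps at least 1 pair together. Chance cannot be excluded for the 16 and 17 lists (19 and 32 splits, highest others 19 and 21, median others 12 and 15).

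Effects of treatment in macrophages minus those in monocytes differed by camera in 7 lists: IFN-gamma response (-0.24), type I interferon response (-0.28), MHC class I presentation (-0.12), inflammatory activation (-0.26), NF-kB targets (-0.20), cell cycle (1.12) and immediate-early genes (-0.21). All 7 had an adjusted p of 0.922 with an estimated correlation, and fry without a block ended all 7 calls (lowest adjusted p = 0.914). Without the 6 control libraries the IFN-gamma difference was 0.03 and the cell cycle difference -0.08. With the fibroblast marker level as a covariate they stayed at -0.23 (camera adjusted p = 0.00253) and 1.07 (camera adjusted p = 1.15e-13). The 1.07 rests on 1 slope for both cell types. Fitted in each cell type alone, the cell cycle score differed between treated and control by -0.63 (SE 0.24) in macrophages and -0.17 (SE 0.48) in monocytes. The 1.07 therefore does not show a larger fall in monocytes at an equal level. With the replicate block, 3 genes differed, Iigp1 (-0.79), Samsn1 (-0.60) and Chpf (2.24).

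Single libraries stood apart from the other 4 of their group in 11 of 176 group values, where chance gives 9, by a gap to the nearest library that exceeded 0.71 of the group's range. The IFN-gamma score of control macrophage replicate 3 was 6.75 against 6.08 for the nearest (0.895 of the range), and its cell cycle score 5.67 against 5.98 (0.828). The MHC class I score of treated monocyte replicate 2 was 9.09 against 8.83 (0.762). The alternative activation score of control monocyte replicate 3 was 4.91 against 4.34 (0.73), and the glycolysis score of treated macrophage replicate 1 was 7.05 against 7.39 (0.726). The lipid handling score of control monocyte replicate 5 was 6.67 against 6.56 (0.755), the complement score of control macrophage replicate 5 was 7.22 against 7.48 (0.717), and the endothelial score of treated macrophage replicate 1 was 1.45 against 0.558 (0.804). The ribosomal protein score of control monocyte replicate 4 was 5.14 against 4.61 (0.935), and that of treated monocyte replicate 5 was 4.79 against 4.33 (0.84). Mrc1 in treated macrophage replicate 2 was 6.84 against 7.68 (0.765).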

How the results depend on the processing

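The alternatives with the fibroblast marker level as a covariate and without 6 control libraries were chosen after seeing the data. The 715 genes in macrophages became 1834 with DESeq2, 1193 with the 2 groups alone, 243 with the replicate block in limma-voom, 2 with the covariate, 70 without the 6 libraries and 2 with block and covariate, and 14 to 1928 without 1 library. Limma-voom with quality weights and no block gave 482, so the move to 243 is not due to the block alone. The 3900 in monocytes became 2019 with the 2 groups alone, 11 with the covariate, 83 without the 6 libraries and 28 with block and covariate, and 1883 to 5277 without 1 library. The 0 interaction genes (980 at an unadjusted p under 0.05) became 5 with DESeq2 and 3 with the block, and 0 to 89 without 1 library. The 6784 and 8294 genes between cell types in control and treated tumours stayed within 1.5 times under these alternatives, at 5846 to 7363 and 7723 to 8643 without 1 library. The correlation of 0.821 became 0.873 among called genes, 0.354 with the covariate and 0.418 without the 6 libraries, and 0.785 to 0.831 without 1 library. Fewer libraries lower the recovery of known changes, as in the simulation, and otherwise the cause was not tested.

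Signs reversed for Ctsk in macrophages (0.003) and Car9 in monocytes (0.014) without the 6 libraries and for Sparc in macrophages with the covariate (0.010). Without the 6 libraries the difference between cell types reversed for the IFN-gamma (0.032), inflammatory (0.052) and NF-kB (0.014) lists and for the cell cycle list, interaction of treatment and cell type (-0.078). For the classical monocyte markers list, not called with all libraries (median 0.06, adjusted p = 0.492), camera's direction turned while the median stayed positive (0.651), and the difference was then called. The cause was not tested. Of the named genes, 45 were called in macrophages and 74 in monocytes, and the covariate ended 43 and 72 of these calls with the direction kept. The replicate block, fitted in limma-voom, ended 14 of them in macrophages and 4 in monocytes. Limma-voom with quality weights and no block ended 12 and 1, so the losses cannot be put down to the block alone.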

Other observations

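The lists in this part were fixed before their values were seen, and they are given by the fit of all libraries. In the complement list, C3 rose by 1.23 (SE 0.26) in macrophages and 0.91 in monocytes and Cfb, the factor B gene, by 0.94 and 1.42. Treated macrophage replicate 4 stood highest for C3, at 10.14 log2 CPM against 8.69 to 9.11 in the other treated macrophage libraries. C3ar1 (0.41) and Itgax (0.53) rose in monocytes. Of 16 complement genes, 2 rose in macrophages (3 adjusted over the list alone, median 0.33, camera adjusted p = 5.93e-05, adjusted p = 0.403 with an estimated correlation) and 5 in monocytes (5 adjusted over the list alone, median 0.25, camera adjusted p = 0.00632, adjusted p = 0.425 with an estimated correlation). Of 27 lysosome genes, 1 rose and 1 fell, Ctsk (-2.46, blocked adjusted p = 0.21), in macrophages (6 and 1 adjusted over the list alone, median 0.20, camera adjusted p = 6.14e-06, adjusted p = 0.403 with an estimated correlation). In monocytes 10 rose, among them Ctsz (0.41), Lamp2 (0.38) and Mitf (0.50) (12 adjusted over the list alone, median 0.27, camera adjusted p = 7.57e-06, adjusted p = 0.425 with an estimated correlation).

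In the lipid handling list, the sterol synthesis gene Sqle fell by 0.63 in macrophages and 1 in monocytes and the fatty acid desaturase gene Scd2 by 0.93 and 1.10, while the sterol sensor gene Nr1h3 rose by 0.85 and 0.87. Lpl fell in macrophages (-0.75), and Abcg1 (0.82) and Plin2 (0.68) rose in monocytes. In the lipid handling list 1 gene rose and 3 fell of 23 in macrophages (4 and 3 adjusted over the list alone, median 0.18, camera adjusted p = 0.444). In monocytes 9 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.39, camera adjusted p = 0.0323, adjusted p = 0.425 with an estimated correlation), and without treated monocyte replicate 5 the list did not pass (adjusted p = 0.0705). Hk3 rose in both (0.88 and 0.85). The glycolysis list had a median of 0.21 in macrophages (1 of 18 higher, 3 adjusted over the list alone, camera adjusted p = 0.00512, adjusted p = 0.594 with an estimated correlation) and 0.17 in monocytes (adjusted p = 0.187), where Pfkm fell (-1.09). Hypoxia genes had medians of -0.05 and 0.05 (adjusted p = 0.866 and 0.73), with P4ha2 (-1.11, blocked adjusted p = 0.060) and Car9 (-0.80) lower in monocytes and Plin2, also in this list, and Pfkfb4 (0.32) higher. Oxidative phosphorylation had -0.02 and -0.04 (adjusted p = 0.866 and 0.611), with Cox6c lower in monocytes (-0.48).

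NF-kB targets in macrophages had a median of 0.19 with 0 of 21 called in edgeR (camera adjusted p = 0.0215, adjusted p = 0.722 with an estimated correlation). Chemokines had 0.25 with 1 of 23 higher (adjusted p = 0.0215, adjusted p = 0.403 with an estimated correlation), and macrophage markers 0.17 with 0 of 25 called (adjusted p = 0.0498, adjusted p = 0.594 with an estimated correlation). These calls ended in 3, 13 and 14 of the 20 fits without 1 library. In monocytes macrophage markers had 0.15 (adjusted p = 0.295), with Csf1r higher and Cd63, Cd81, Fcrls and Vcam1 lower, genes named after their values were seen. Classical monocyte markers had 0.39 and 0.33 in macrophages and monocytes (adjusted p = 0.109 and 0.069). Nonclassical markers had 0.21 (adjusted p = 0.109) and 0.60 (adjusted p = 0.0358, adjusted p = 0.425 with an estimated correlation). The monocyte nonclassical call ended in 3 of 20 fits without 1 library.

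T cell markers had medians of 0.14 and 0.22 in macrophages and monocytes (adjusted p = 0.866 and 0.628), with a median level of 1.04 and 1.09 CPM in treated libraries, and 1 of the 18 stands in another list. Cytotoxic and NK markers had 0.64 (adjusted p = 0.109) and 0.85 (adjusted p = 0.0275, adjusted p = 0.624 with an estimated correlation, blocked fry adjusted p = 0.0965), and the monocyte call ended without control monocyte replicate 2 (0.74, adjusted p = 0.0939) and without treated monocyte replicate 5 (0.36, adjusted p = 0.155). Gzmb, a granzyme gene chosen after its values were seen, was at 3.87 and 7.26 CPM in control and treated macrophages and 6.6 and 12.4 in monocytes. Neutrophil markers had 0.59 and 0.35 (adjusted p = 0.0785 and 0.0815), dendritic cell markers 0.20 and 0.05 (0.254 and 0.814), and B cell markers -0.03 and -0.14 (0.866 and 0.628). Mast cell, basophil and eosinophil markers had 0.15 and -0.88 (0.866 and 0.193), epithelial tumour cell markers 0.24 and -0.09 (0.617 and 0.731), endothelial markers -0.40 and -0.21 (0.904 and 0.80), and erythroid markers -0.25 and 0.29 (0.444 and 0.701). Ribosomal protein genes had -0.21 (adjusted p = 0.000449, adjusted p = 0.667 with an estimated correlation) and -0.29 (adjusted p = 6.2e-05, adjusted p = 0.565 with an estimated correlation), and the macrophage call ended without control macrophage replicate 1 (-0.04, adjusted p = 0.128). Replication-dependent histones had -0.45 (adjusted p = 0.0498, adjusted p = 0.429 with an estimated correlation) and -0.99 (adjusted p = 0.00881, adjusted p = 0.425 with an estimated correlation), and the macrophage call ended in 6 of 20 fits without 1 library (adjusted p up to 0.126). Mitochondrially encoded genes had -0.36 and -0.24 (adjusted p = 0.288 and 0.304). Immediate-early genes had -0.03 (adjusted p = 0.866) and 0.19 (adjusted p = 0.0158, adjusted p = 0.56 with an estimated correlation, without control monocyte replicate 4 adjusted p = 0.0975).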
